A study of Lacticaseibacillus paracasei with 6 samples.

How the data were processed

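The series holds RNA-seq libraries of Lacticaseibacillus paracasei L9, 3 of the group L9_melA and 3 of L9_0968. Per the labels' protocols, total RNA was depleted of ribosomal RNA with probes, and strand-marked libraries were made by placing dUTP in the second strand and degrading it. Reads were aligned with Bowtie2 2.2.3, per the submitters' processing notes. The counting tool, its strand setting, the annotation release and the test behind the deposited comparison are not given in the sources used here.

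One table of the whole series was used. The deposited read counts per gene are whole numbers, named as counts per the file headers, and their totals differ between libraries. They stand beside FPKM values and a comparison of the groups. The deposited FPKM values equal counts divided by gene length and library total, times 1 factor per library between 0.951 and 1.14, so the authors' FPKM carry a scaling factor of their own beside the library total. The deposited log2 fold changes and p-values of the authors' own comparison have no value in 339 genes, which are those with under 2 counts over the 6 libraries. They were used only to count the authors' calls and to compare their fold changes with those found here. There were 6 columns of normalized values per library that were not used. Coordinates are those of the table, on its single chromosome sequence, and no genome sequence was used. The table has 60 tRNA rows and 15 ribosomal RNA rows, and 325 of its 2993 rows were at 0 in every library. No row was without a gene name.

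Each column was matched to its library through the labels. Total counts per library were 3019646, 2770574 and 2885885 in L9_melA and 2959618, 2902410 and 3036529 in L9_0968. At these depths a count of 0 allows up to 0.988 to 1.08 CPM (3 counts over the library total, without the TMM factor), a limit that covers counting error only. No 2 libraries of a group agreed within sampling noise: the chi-square of their counts per degree of freedom, over genes with at least 10 counts in the pair, was 6.36 to 79.4. L9_melA replicate 1 differed most from its group (72.6 and 79.4, against 6.36 between replicates 2 and 3).

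The counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, filterByExpr, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment over the 2467 genes kept, with a threshold of 0.05. The other 526 rows were not tested. No covariate was used. The standard error of a log2 fold change comes from the group variances of log2 CPM with a prior count of 2. In simulated counts with 200 changed genes among 2467, made from the means and totals of these libraries for L9_0968 against L9_melA, this test recovered 26.9% of 1.5-fold, 82.1% of 2-fold and 98.5% of 4-fold changes, and 2.8% of its calls were false. Small changes are therefore often missed. The simulated libraries of a group differed at random only, with none set apart as L9_melA replicate 1 was, and a single draw was made. The rates may differ in these data.

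Gene lists, 22 in all, were defined by symbols and words of the product names before the data were examined, as were the tests, the alternatives and the rule for naming genes. Lists built on words can take in genes of other function. Lists with at least 3 tested genes, 20 of them, were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and adjustment over the 20 lists, and again with an estimated correlation and with fry. In the same kind of simulation, a list lowered 1.5-fold was called and 0 of 19 others were. The simulated genes vary independently, so this says nothing of lists whose genes vary together.

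The rule named the locus carrying the number of the L9_0968 label and its 3 neighbours on either side, rows for melA or alpha-galactosidase, the 10 largest increases and the 10 largest decreases among called genes with a described product and no overlap of the groups, up to 4 called members of each list or the member with the smallest p, and every member of the lists Lia and PspC family and D-alanylation. As no row carried it, the neighbours of liaX were named in place of those of the targeted locus, after the values were seen.

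Alternatives were size factors of DESeq2 within edgeR, library totals, no count filter, a mean of at least 50 counts, DESeq2 1.42.0, limma-trend on log2(FPKM + 1) with pseudocounts of 0.1 and 5 as well and a minimum mean FPKM of 1, the replicate number as a block, and each library left out in turn. A fit without tRNA and ribosomal RNA rows was added after seeing the data. Of the 70 called genes, 15 overlap a neighbour on the same strand, by at most 20 bp, and 0 overlap a row on the other strand. Reads of near-identical copies, as may be the case for tRNA genes, could be split between rows, and their values are uncertain. Whether the 2 pstB rows are alike in sequence was not checked. The result of 1 called gene is not reported here, and the counts include it.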

Results

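RNA was sequenced from cultures of Lacticaseibacillus paracasei L9, a lactic acid bacterium, to ask which transcripts differ between mutants of this strain under bile salt stress. There were 2 groups of 3 libraries, named L9_melA and L9_0968 in the labels. Per the labels, both are mutants, grown in MRS broth at 37 °C with erythromycin at 10 µg/mL, exposed to 0.05% of the glycine conjugate of deoxycholate, a bile salt, and collected in the logarithmic phase. There was no library without bile salt and none marked as the unmodified strain, so each value below is a contrast of the mutants in bile salt. A rise in L9_0968 therefore cannot be told apart from a fall in L9_melA, or the reverse. The deposited table gave 2993 genes on a single chromosome, and total counts per library ran from 2770574 to 3036529. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Unless another error is named, levels are CPM, counts scaled to library size with TMM factors, given as mean ± SD with n = 3, and log2 fold changes are L9_0968 over L9_melA with the standard error.

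The genes that the group names point to were examined first. No row of the table carried the number of the L9_0968 label in its identifier or symbol, and no row had the symbol melA, so neither group name could be tied to a row. The annotation held 3 rows for alpha-galactosidase, the enzyme that releases galactose from alpha-galactosides. LPL9_RS10665 (2180659 to 2182881, plus strand) had 101 ± 8.37 CPM in L9_melA and 162 ± 43.5 in L9_0968, a log2 fold change of 0.69 ± 0.22 with an adjusted p of 0.102 in edgeR's quasi-likelihood test. LPL9_RS05340 had a log2 fold change of 0.56 ± 0.26 and LPL9_RS05330 one of 0.67 ± 0.69, and neither passed the test. LPL9_RS05330 rests on 3 to 21 reads per library, and had 0.14 to 1.78 when 1 library was left out. The group labels were therefore not checked by a targeted gene.

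The largest difference lay at liaX, which encodes the surface protein that the table annotates as daptomycin-sensing and which the series title names. liaX (LPL9_RS04880, 984352 to 985833, plus strand) was at 9362 ± 2124 CPM in L9_melA and 45.1 ± 4.09 in L9_0968. The 3 L9_melA libraries held 18237, 29906 and 30992 reads of this gene, and the 3 L9_0968 libraries held 154, 129 and 132. The log2 fold change was −7.70 ± 0.22 (adjusted p = 1.2e-06, edgeR). Just downstream on the same strand, the hypothetical protein gene LPL9_RS04885 fell with a log2 fold change of −5.54 ± 0.20, and the phage holin family gene LPL9_RS04890 with −5.67 ± 0.30. Upstream, the phosphate transporter genes pstB (2 rows) and phoU had log2 fold changes of −0.19, −0.18 and −0.16, and downstream hprK, the HPr kinase gene, had −0.18, none past the threshold. The deposited comparison names this group LPL9_0968, with the prefix of the table's gene identifiers, so the name may be a locus number. No identifier carries that number, and the gene altered in L9_0968 could not be identified from its name. A fall caused by the mutation itself at this locus therefore cannot be told apart from a regulatory response. The neighbours were taken from 3 genes on either side of liaX, a choice made after the values were seen, because no row carried the number the fixed rule asked for.

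**Figure D1:**
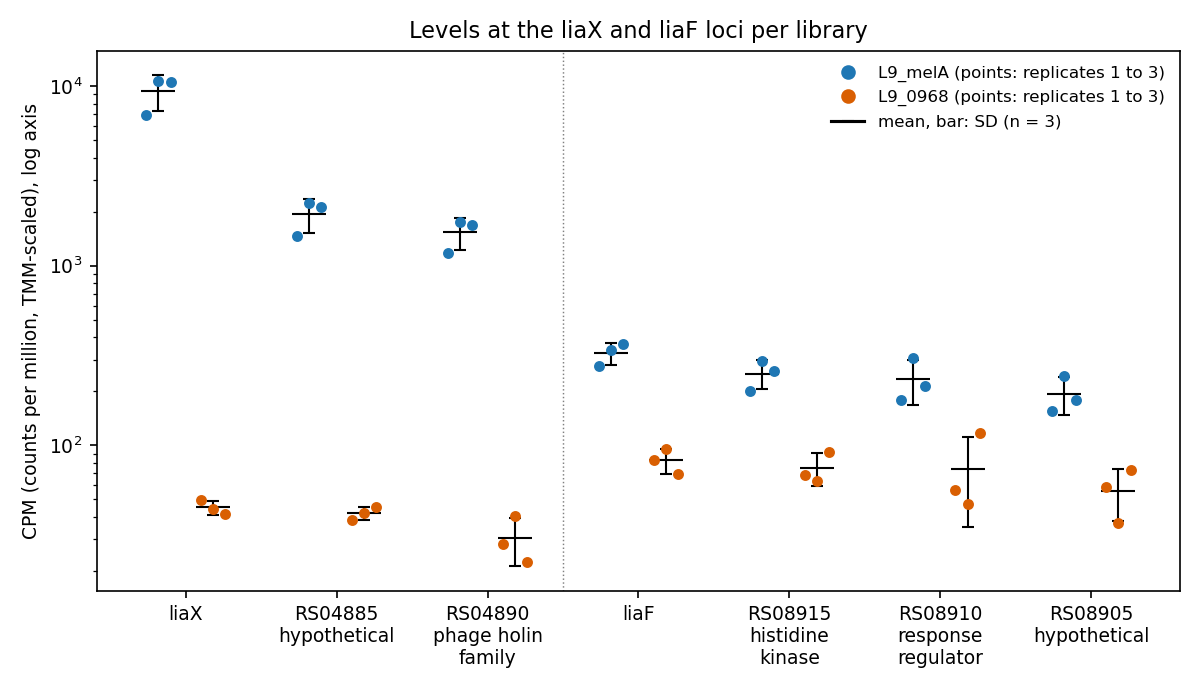
CPM (TMM-scaled counts, log axis) of 3 genes at the liaX locus, left of the dotted line, and 4 genes at the liaF locus in each library; points are libraries, long ticks are group means and bars are SDs (n = 3). For each of the 7 genes the 3 L9_0968 libraries lie below the 3 L9_melA libraries, and for liaX the means are 45.1 and 9362.

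The genes of the liaF locus, which encode a membrane protein and a sensor kinase with its response regulator, also fell in L9_0968. liaF (LPL9_RS08920, 1812188 to 1812892, minus strand) went from 327 ± 46.6 to 82.8 ± 13.2 CPM, a log2 fold change of −1.98 ± 0.18 (adjusted p = 0.000119, edgeR). The sensor histidine kinase LPL9_RS08915 had −1.75 ± 0.23, the response regulator LPL9_RS08910 had −1.66 ± 0.46 and the hypothetical protein LPL9_RS08905 had −1.78 ± 0.34. The response regulator is the least certain of the 4: its adjusted p was 0.0356, and it lost its call with libraries scaled to their totals (0.057), without L9_melA replicate 2 or 3 (0.10 and 0.065) and without L9_0968 replicate 1 or 2 (0.15 and 0.089). greA, next to liaF, and the rhomboid protease gene LPL9_RS08890 had log2 fold changes of −0.04 and 0.01. liaX and liaF were the 2 members of the list named Lia and PspC family, and the title of the series had named this system when that list was written.

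**Figure D2:**
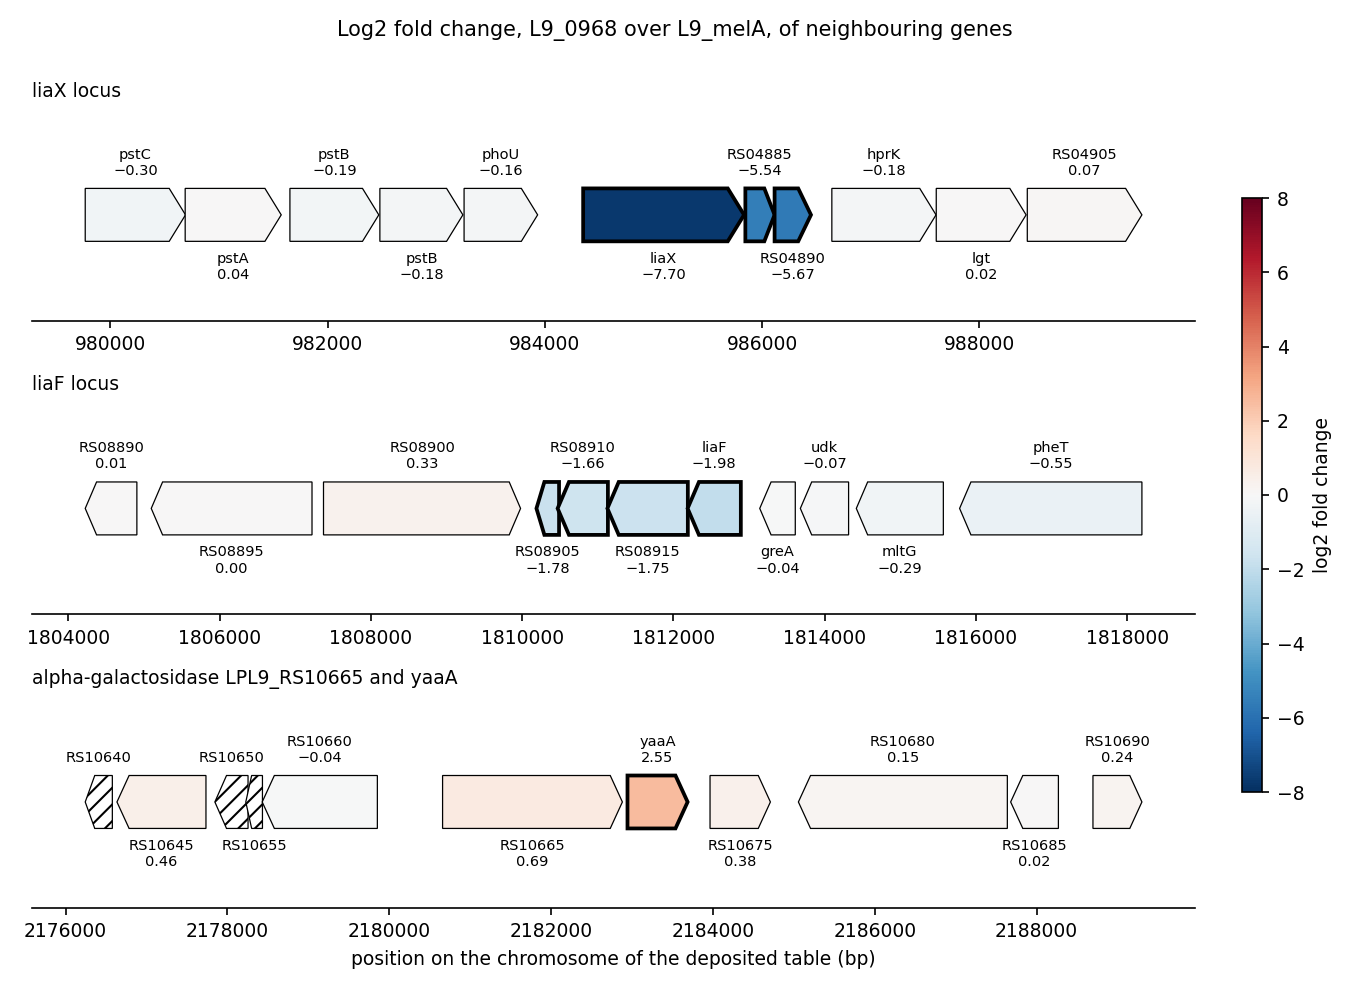
Maps of 3 stretches of the chromosome with each gene drawn as an arrow to scale along the horizontal axis (position in bp), coloured and numbered by its log2 fold change, L9_0968 over L9_melA; thick outlines mark genes past the adjusted p threshold, and hatched genes were not tested. The 3 genes from liaX onward have −7.70, −5.54 and −5.67, the 4 genes from LPL9_RS08905 to liaF have −1.98 to −1.66, and of the stretch around LPL9_RS10665 yaaA alone is past the threshold, with 2.55.

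Across the transcriptome, 70 of 2467 tested genes changed at an adjusted p under 0.05, of which 25 were higher and 45 lower in L9_0968. At least 2-fold changes numbered 53, with 18 higher and 35 lower. For each of the 70 genes the 3 libraries of one group all lay on one side of the 3 of the other. This was so for 589 tested genes (23.9%), against 10% by chance for 3 against 3. The counts depended on the tool and on single libraries. DESeq2 called 169 genes, 77 higher and 92 lower. The number of higher genes was 13 without L9_melA replicate 2 and 15 without L9_0968 replicate 1, and the total without those libraries was 49 and 47. Of the 70 genes, 45 were called in each of the 17 settings tried. The authors' deposited table called 164 genes at the same threshold, 77 higher and 87 lower, and held all 70 genes called here with the same signs. It covers the same libraries, and its log2 fold changes correlated with those here at a Pearson r of 1. The shared signs are therefore not separate evidence.

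**Figure D3:**
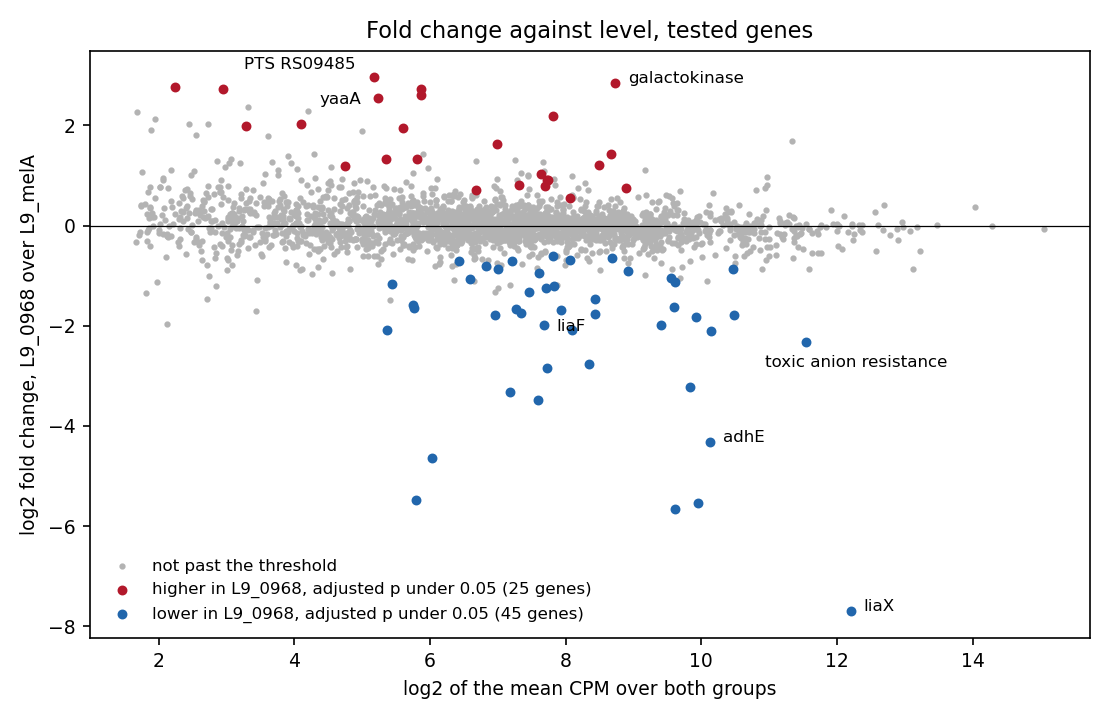
Log2 fold change, L9_0968 over L9_melA, of the 2467 tested genes (vertical axis) against the log2 of their mean CPM over both groups (horizontal axis); red and blue points are the 25 higher and 45 lower genes past the threshold. liaX, at −7.70, lies farthest from 0.

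Beyond the lia loci, the largest decrease among called genes with a described product was at LPL9_RS08215, the ATP-binding gene of an ABC transporter. Genes without a described product, such as LPL9_RS09655 (−3.48), are left out of this ranking. LPL9_RS08215 held 232, 364 and 315 reads in the L9_melA libraries and 2, 3 and 17 in the L9_0968 libraries. Its log2 fold change was −5.48 ± 0.70, with −6.95 to −5.03 when 1 library was left out. The permease gene beside it, LPL9_RS08210, had −4.63 ± 0.28, with 11, 17 and 18 reads in L9_0968. adhE, which encodes the bifunctional enzyme that reduces acetyl-CoA to ethanol, fell from 2139 ± 257 to 108 ± 32.7 CPM, a log2 fold change of −4.31 ± 0.28 (adjusted p = 9.6e-06, edgeR). LPL9_RS06865, annotated as the redox-sensing repressor Rex, had −3.33 ± 0.23. The neighbours LPL9_RS13250, a TPM domain protein, and LPL9_RS13255, of the LemA family, had −2.85 ± 0.16 and −2.76 ± 0.12. The toxic anion resistance gene LPL9_RS07030, abundant in L9_melA at 4984 CPM, had −2.32 ± 0.24, and LPL9_RS07035 beside it had −2.10 ± 0.27. spxA, the gene of a regulator of the thiol stress response, had −1.13 ± 0.19, and plsY, which encodes an acyltransferase of phospholipid synthesis, had −0.72 ± 0.10. The call of plsY was lost with libraries scaled to their totals (adjusted p = 0.095) and without each library other than L9_0968 replicate 3 (0.059 to 0.15).

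The 10 largest increases among called genes with a described product were 3 phosphotransferase system genes, galactokinase, yaaA, aspD and 4 tRNA genes. Galactokinase (LPL9_RS03555), the first enzyme of the Leloir pathway, rose from 103 ± 7.24 to 745 ± 237 CPM, a log2 fold change of 2.85 ± 0.28 (adjusted p = 7.83e-05, edgeR). A stretch at 1922302 to 1925436 on the minus strand held the phosphotransferase system genes LPL9_RS09485, LPL9_RS09490 and LPL9_RS09470, with log2 fold changes of 2.96 ± 0.48, 2.73 ± 0.32 and 1.95 ± 0.27. yaaA, annotated as a peroxide stress protein, rose from 10.9 ± 1.48 to 64.0 ± 10.5 CPM (2.55 ± 0.17). The aspartate 4-decarboxylase gene aspD had 2.18 ± 0.66 with an adjusted p of 0.0422, and lost its call in limma-trend at each pseudocount (adjusted p 0.064 to 0.079) and without L9_melA replicate 1, 2 or 3 or L9_0968 replicate 2 (0.063 to 0.086). The 4 tRNA genes lie within a single cluster, for phenylalanine (LPL9_RS04435, 2.76), proline (LPL9_RS04370, 2.72), isoleucine (LPL9_RS04380, 2.04) and arginine (LPL9_RS04365, 1.99). These rest on few reads: the tRNA-Phe row had 1, 3 and 6 in L9_melA and 24, 13 and 40 in L9_0968. Each of the 4 lost its call without at least 1 of the libraries, and 3 of them in limma-trend as well, and 50 of the 60 tRNA rows share product and length with another tRNA row, so reads could be split between copies.

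Of the 20 fixed lists large enough to test, fatty acid synthesis and ribosomal proteins passed camera with its preset correlation, both lower in L9_0968 (adjusted p = 1.5e-06 each). Neither call held with an estimated correlation (adjusted p = 0.98 each). Nor was the number of lists called peculiar to the real grouping: each of the other 9 splits of the 6 libraries into 3 and 3 called 2 to 7 lists by the same test. Of the 14 members of the fatty acid list, 2 fell at an adjusted p over all genes, and 11 were lower when adjusted over the list alone. DESeq2 called 10 lower. fabZ had −1.07 ± 0.26 and accD −0.70 ± 0.14, which encode a dehydratase of the elongation cycle and a subunit of acetyl-CoA carboxylase. The median was −0.84. The 10 members between 2216311 and 2225884 had log2 fold changes from −1.34 to −0.70 and lie on 1 strand within 11 genes, so they need not be independent of each other, and the other 4 members had −0.56 to 0.26. accD and fabZ each kept the call without L9_melA replicate 3 and lost it without each of the other 5 libraries. With all libraries kept, accD also lost it with library totals (adjusted p = 0.072) and in limma-trend (0.05 to 0.056).

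None of the 58 ribosomal protein genes was called, by edgeR over all genes or adjusted over the list alone, and their median log2 fold change was −0.40. At an unadjusted p under 0.05 there were 19. DESeq2 called 6, and edgeR with the replicate number as a block called 4, all lower. rpmB, the member with the smallest p, had −0.87 ± 0.26 and was called by DESeq2 (adjusted p = 0.0052). L9_melA replicate 1 stood apart here. The mean level of the ribosomal list, on a log2 scale relative to the mean of the 6 libraries, was 0.64 in that library and between −0.24 and −0.06 in the other 5. Without it the list's median was −0.10 and its adjusted p 0.26. The same library had the lowest scaling factor, 0.874 against 1.01 to 1.05, and the lowest level of heat shock genes, −0.57 against 0.03 to 0.21. The fatty acid list was also highest in it, at 0.74, against 0.33 and 0.07 in L9_melA replicates 2 and 3. Without it the list's median was −0.61 and 0 of the 14 members were called over all genes. Camera at the preset correlation then gave an adjusted p of 8.8e-05 (range over the alternatives 1.4e-08 to 0.98). The tests with an estimated correlation and with fry were not run without that library, so this p does not settle whether the fall outlasts its removal.

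**Figure D4:**
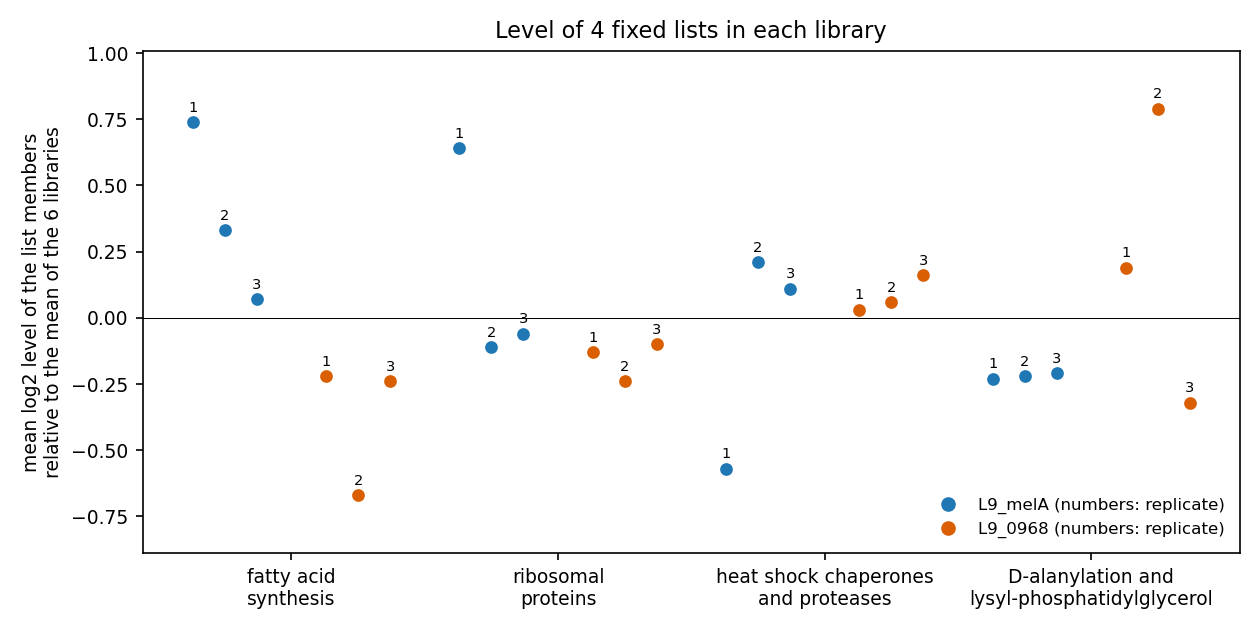
Mean log2 level of the members of 4 fixed lists in each library, relative to the mean of the 6 libraries (vertical axis); numbers beside the points are replicate numbers and colours are groups. L9_melA replicate 1 has 0.64 for ribosomal proteins and −0.57 for heat shock genes, and L9_0968 replicate 2 has 0.79 for the D-alanylation list.

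The genes of cell surface charge were not past the threshold. All 6 members of the list of teichoic acid D-alanylation and lysyl-phosphatidylglycerol synthesis had log2 fold changes above 0, from 0.08 for mprF to 1.15 for the dltX-type gene LPL9_RS04155, with dltA at 0.69 ± 0.48, dltB at 0.61 ± 0.33, dltC at 0.40 ± 0.26 and dltD at 0.26 ± 0.17. Leaving out 1 library gave 0.20 to 1.02 for dltA, 0.26 to 0.84 for dltB, 0.12 to 0.58 for dltC, 0.09 to 0.40 for dltD, 0.44 to 1.53 for LPL9_RS04155 and −0.01 to 0.17 for mprF. With all libraries none was called by edgeR or DESeq2, and 2 had an unadjusted p under 0.05. The members other than mprF lie side by side on the plus strand, from 854631 to 859167, so they need not be independent of each other. The list's adjusted p was 0.12 in camera. L9_0968 replicate 2 was highest, at 0.79 on the relative log2 scale, and replicate 3 of the same group was lowest, at −0.32. The adjusted p was 0.00033 without L9_0968 replicate 3 and 0.58 without replicate 2, so the list's call turned on single libraries (range over the alternatives 0.00033 to 0.98). No member of the lists of peptidoglycan synthesis (25 tested), cell wall hydrolases (10), teichoic acid and wall polysaccharide synthesis (9), and antimicrobial peptide and multidrug transport (6) was called over all genes, by edgeR or DESeq2, with camera adjusted p of 0.85, 0.85, 0.99 and 0.19. At an unadjusted p under 0.05 they held 2, 2, 2 and 1. The hydrolase list was built on words, and 4 of its 10 genes encode synthesis enzymes, murD and mraY among them, while the P40 gene LPL9_RS00110 and the P75 gene msp1, annotated as cell wall hydrolases, are outside it; neither of these was past the threshold over all libraries, both were without L9_melA replicate 1, and they were looked at after their values were seen. Adjusted over the list alone, 1 multidrug transporter was higher, LPL9_RS11360 (0.49 ± 0.06). The only row of the bile salt hydrolase family, LPL9_RS02345, had −0.08 ± 0.12.

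The remaining lists held few calls. Of 83 phosphotransferase system genes 3 were higher and 1 lower, the mannitol transporter gene LPL9_RS14740 with −0.95 ± 0.22, over all genes and adjusted over the list alone, and camera gave an adjusted p of 0.19, with 0.025 without L9_0968 replicate 3 and up to 0.63 without another library, and 0.98 with an estimated correlation. The call of LPL9_RS14740 was lost with library totals and in limma-trend (0.052 to 0.06) and without L9_melA replicate 2 or L9_0968 replicate 1 or 3 (0.087 to 0.15). Of 30 two-component regulators the 2 genes beside liaF fell (0.85). Of 23 sortase and surface protein genes 2 fell, LPL9_RS16045 with −2.08 ± 0.18 and LPL9_RS03250 with −1.24 ± 0.28, and adjusted over the list alone 4 were lower and 1 higher (0.85). LPL9_RS03250 lost its call without L9_0968 replicate 1 (0.11) or 3 (0.051). Among 13 phospholipid genes plsY fell (0.85), and among 20 genes of oxidative stress spxA fell, with 2 lower and 1 higher adjusted over the list alone (0.9). The lists of heat shock and of prophage genes each held 1 lower gene that was taken in by words and may have another function. These were hemW, annotated as a heme chaperone (−1.46 ± 0.11), and the holin family gene of the liaX locus. Their adjusted p was 0.85 each. DESeq2 called 6 higher and 1 lower in the phosphotransferase list, 4 lower and 1 higher among surface proteins, 2 lower and 1 higher in oxidative stress, 2 lower in heat shock, 2 higher and 1 lower in prophage, 2 lower among two-component regulators and 1 lower among phospholipid genes. The words of the lists missed called genes of related function, and the examples given here were noticed after their values were seen. The protease genes hslV and hslU (−2.08 ± 0.09 and −1.82 ± 0.06) are outside the heat shock list, and yaaA is outside oxidative stress. The Nramp family metal transporter LPL9_RS00185 (0.76 ± 0.04) is outside metal ions. brnQ, of branched-chain amino acid transport, is outside amino acid uptake (0.71 ± 0.14, adjusted p 0.0053 to 0.16 over the alternatives). Other called genes of this kind are not given here, so a list without a call does not show that its process was unchanged. No gene of the lists of ATP synthase (8 tested), glycolysis (17), purine synthesis (16), pyrimidine synthesis (12), amino acid and peptide uptake (31) and metal ion uptake (28) was called by edgeR, with camera adjusted p of 0.85, 0.98, 0.66, 0.85, 0.85 and 0.99. At an unadjusted p under 0.05 they held 0, 0, 2, 1, 1 and 8, and DESeq2 called 1, in the metal ion list, lower. The signs of the median, mean and camera test differed for the lists of wall polysaccharide (−0.11, 0.13, up), oxidative stress (0.08, 0, down), surface proteins (0.14, −0.14, down), prophage (0.03, −0.29, up) and metal ions (−0.08, −0.04, up).

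**Figure D5:**
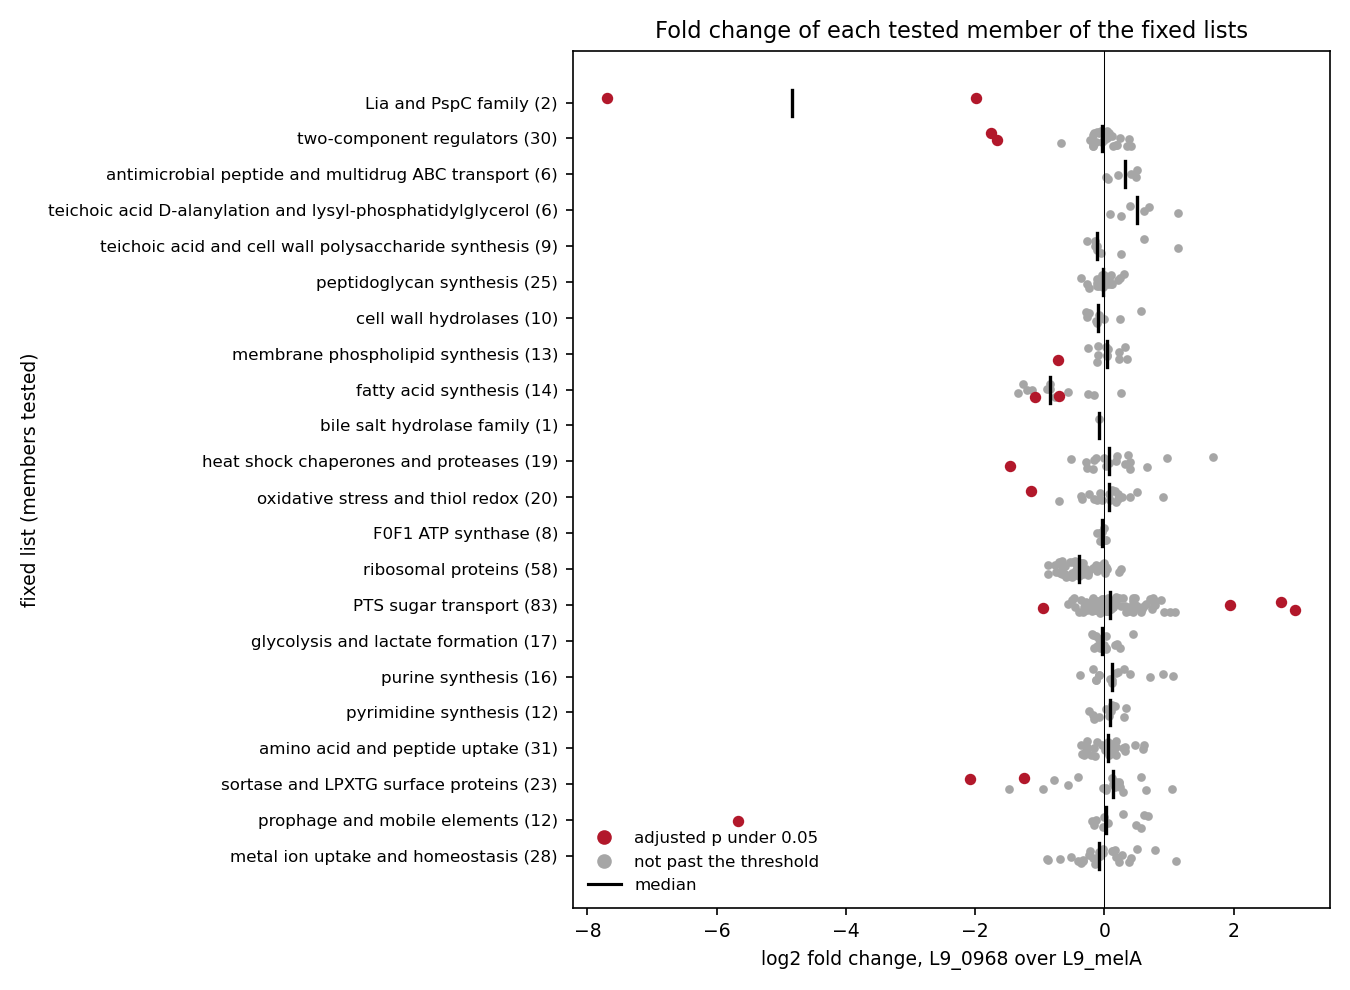
Log2 fold change, L9_0968 over L9_melA (horizontal axis), of each tested member of the 22 fixed lists, with the number tested in brackets; red points are past the adjusted p threshold over all genes, grey points are not, and black bars are medians. The fatty acid list has a median of −0.84 with 2 members past the threshold, and the ribosomal list has −0.40 with 0.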

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

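The fit without tRNA and ribosomal RNA rows was chosen after the results were seen, and the other settings before. Directions of the 70 calls did not turn in any of the 16 alternatives, and 45 of the 70 were called in each. The number of genes called was 169 with DESeq2 (77 higher, 92 lower, and 83 at least 2-fold, of which 36 higher) and 119 with the replicate block (52 higher, and 36 higher at least 2-fold), and the cause was not tested. Both were run on the same libraries as the 70 calls, which DESeq2 held in full and the block in 69 cases. Other settings, except those that leave out a library, gave 61 to 72 calls. Leaving out 1 library at a time, which also leaves fewer samples, gave 47 to 71 calls, 13 to 28 higher and 32 to 47 lower, and 44 to 57 at least 2-fold, of which 11 to 21 higher. The lowest totals came without L9_0968 replicate 1 (47) and without L9_melA replicate 2 (49).

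Whether the replicate numbers pair the samples was not settled. Deviations from the group means correlated by 0.129, −0.129 and 0.0268 across genes for replicates 1, 2 and 3, values too low to show a pairing. They cannot exclude one, and the block raised the number of calls to 119. The labels name no shared culture or day. With the replicate block the D-alanylation list passed (adjusted p = 0.044), so that 3 lists were called, but without the block it had 0.98 with an estimated correlation and 0.58 with fry.

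The number of lists called was 2 in most settings. It was 0 with an estimated correlation, 1 with fry, which tests each list alone, and 1 to 4 when a library was left out, with 1 without L9_melA replicate 1 and 4 without L9_0968 replicate 3, where D-alanylation (adjusted p = 0.00033) and phosphotransferase genes (0.025) were added. The list fry called was two-component regulators (adjusted p = 0.024). Its 2 called members were the genes beside liaF, its median log2 fold change was −0.04, and 13 of its 30 members were above 0. The fry call therefore does not show a fall of two-component regulators in general. For fatty acid synthesis fry gave 0.21, and for ribosomal proteins 0.58. Some lists that were not called changed direction, and the cause was not tested. For wall polysaccharide synthesis the adjusted p there was 1 with DESeq2 size factors, without a count filter and with DESeq2, 0.98, 0.97 and 0.98 with limma-trend at pseudocounts of 1, 0.1 and 5, 0.83 with fry, and 0.84 to 0.99 over the libraries left out. For oxidative stress it was 1 without a count filter, 0.98, 0.97 and 0.98 with limma-trend, and 0.75 to 0.99 over the libraries left out. With library totals it was 1 for peptidoglycan synthesis, 1 for glycolysis and 0.95 for metal ions. With fry it was 0.83 for heat shock, 0.44 for prophage and 0.82 for metal ions. Over the libraries left out the adjusted p ranged from 0.29 to 0.99 for heat shock, 0.097 to 1 for ATP synthase, 0.84 to 0.99 for glycolysis, 0.12 to 0.99 for purine synthesis, 0.58 to 0.99 for pyrimidine synthesis and 0.93 to 0.99 for metal ions.

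LPL9_RS10665 was called with DESeq2 (log2 fold change 0.68, adjusted p = 0.041, range over the alternatives 0.041 to 0.22). LPL9_RS02345 had a log2 fold change of 0 with library totals and of −0.18 to 0.04 over the libraries left out, and mprF had −0.01 to 0.17, with −0.01 without L9_melA replicate 1. Scaling to library totals moved the median of all genes to 0.089. In a simulation at the depth and spread of these libraries, in which no library stood apart, 26.9% of 1.5-fold changes were recovered. Whether depth, spread or the number of libraries limits this was not tested. At these depths a count of 0 allows up to 1.08 CPM, taken without the TMM factor.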

Other observations

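The tests of the ribosomal list, of yaaA and of the tRNA cluster were chosen after the results were seen, and the counts of other splits were planned. The genes of the next paragraphs were picked after their values were seen.

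Many of the called genes lie side by side. Of the 70, 39 stand in 15 runs of neighbours on 1 strand that moved in 1 direction, and 24 adjacent pairs compare with a mean of 0.952 and a highest value of 7 when calls were placed at random among tested genes (1e-04, the smallest p that 10000 one-sided permutations can give). The longest run, of 5 higher genes, began with galactokinase (LPL9_RS03555). It also held the uridylyltransferase LPL9_RS03565 (log2 fold change 1.21 ± 0.19), the LacI family regulator LPL9_RS03570 (1.03 ± 0.06) and galactose mutarotase LPL9_RS03575 (0.91 ± 0.14). lacB, of the tagatose route of galactose use, had 0.82 ± 0.18, and was not called without any 1 of the L9_melA libraries or without L9_0968 replicate 1 (adjusted p 0.078 to 0.13). Lower runs held the protease genes hslV and hslU (−2.08 ± 0.09 and −1.82 ± 0.06) and hemW with ribF (−1.46 and −1.33). An acylphosphatase gene, LPL9_RS08965, stood beside yidC, which encodes an insertase of membrane proteins (−1.77 and −0.86), and yidC was not called without L9_0968 replicate 1 (adjusted p = 0.07). An ABC transporter, LPL9_RS09645, stood with the hypothetical gene LPL9_RS09655 (−1.99 and −3.48).

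For 4 genes annotated as hydrolases or peptidases, none of them in the fixed lists, L9_melA replicate 1 differed from the other libraries of its group. The P40 gene LPL9_RS00110 had 2352 CPM in L9_melA replicate 1, 841 and 875 in replicates 2 and 3, and 2341, 2318 and 1980 in L9_0968. Over all libraries its log2 fold change was 0.71 ± 0.49 (adjusted p = 0.381). Without that library it was 1.36 (0.00028, range over the alternatives 0.00028 to 0.61). The hydrolase gene LPL9_RS11340 had 3478, 427 and 426 CPM in L9_melA and 2992, 2806 and 1841 in L9_0968. Over all libraries its log2 fold change was 0.82 ± 1.03 (adjusted p = 0.627), and without that library it was 2.57 (0.00028, range over the alternatives 0.00028 to 0.84). The P75 gene msp1 and the C40 peptidase gene LPL9_RS10415 had log2 fold changes of 0.20 and 0.74, neither past the threshold, and 0.49 and 1.18 without that library, where both passed it (0.029 and 0.0054). None of the 4 is a call of the planned test, and they were picked for how 1 library deviates. The edgeR fit without that library newly called 17 genes. Among them were also the hydrolase gene LPL9_RS01260 (0.94, adjusted p = 0.0011) and, lower, the metalloprotease gene LPL9_RS10065 (−0.85, 0.013).

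The lower ribosomal list may rest on L9_melA replicate 1. Without that library the camera adjusted p was 0.26 (range over the alternatives 8.6e-12 to 0.98) and the median went from −0.40 to −0.10. The scaling of the libraries was not decided: with library totals the median relative to that of all genes was −0.37, but scaling moves all genes nearly alike, so that this value says nothing for or against it. A difference between the mutants was not excluded. rpmB had −0.59 without that library (adjusted p = 0.048, edgeR), but it was picked as the member with the smallest p. Its value therefore says nothing of the list as a whole.

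yaaA lies just downstream of the alpha-galactosidase gene LPL9_RS10665 on the same strand, and was higher in L9_0968. Its counts were 28, 35 and 28 in L9_melA and 192, 221 and 173 in L9_0968. A binomial test of the pooled counts for counting noise, multiplied by the 2467 tested genes because yaaA was picked from among them, gave 1.5e-76. This outcome was fixed in advance, since yaaA was picked as a call of edgeR, which allows for more than counting noise. The binomial test covers counting noise only, not the spread between cultures. A candidate explanation is a change at the alpha-galactosidase locus in the L9_melA strain that reaches yaaA. It cannot be told apart from a regulatory difference between the mutants: LPL9_RS10665 had a log2 fold change of 0.69 that missed the threshold over all genes in edgeR (adjusted p = 0.102) and passed it in DESeq2 (0.041), with 0.041 to 0.22 over the alternatives, and the table gives no sequence of the strains.

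The tRNA cluster at 893774 to 896137 has 25 rows, of which 23 were tested, with a median log2 fold change of 1.43. Of the 23, 4 were called and 20 had an unadjusted p under 0.05. A better recovery of short RNA in the L9_0968 libraries could raise all tRNA rows alike. The 15 other tested tRNA rows had a median of 0.46. The 4 called rows drew attention to the cluster and were left out of the test. The 19 rows that were not called had a median of 1.34, higher than the 15 (p = 7e-05, 100000 one-sided permutations of rows). Rows of 1 cluster are not independent, so this p is too small. Leaving out the called rows does not undo the choice of a cluster seen to be high, so the test cannot decide on recovery. The values show only that the cluster rose more than the other tRNA rows. All tRNA rows together took 0.0407% to 0.0573% of the counts in the L9_melA libraries and 0.0687% to 0.0948% in the L9_0968 libraries. Without L9_melA replicate 1 the cluster's median was 1.34, so that library is not the whole cause. The median moved with single libraries, from 1.34 to 2.12, the latter without L9_melA replicate 3, and a difference between the mutants was not tested further.

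The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 70 genes, 53 of them at least 2-fold, and the highest count of any other split was 0 for both, so that 1 of the 10 splits reached each real count. For the fixed lists the real split called 2, the highest other split called 7, and all 10 of the splits called at least 2.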
